A study of Saccharomyces cerevisiae with 14 samples.

How the data were processed

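The series measured RNA of budding yeast (Saccharomyces cerevisiae) by high-throughput sequencing. Per the labels' protocols, 600 ml cultures grown at 30 °C to an OD600 of 0.8 received 500 µM 4-thiouracil (4tU) and were frozen in cold methanol after 1.5, 2.5 or 5 min. RNA was extracted with hot phenol, 2 mg were biotinylated, and the thiolated RNA was bound to streptavidin beads and eluted with a reducing agent, per the labels' protocols. Libraries were made by random priming and amplified over 16 to 20 PCR cycles, per the labels. The same labels place 6 random bases at the start of the adapter barcode; whether reads were collapsed on them is not given in the sources used here. STAR 2.4.2a and genome build R64 are named in the submitters' processing notes with no role.

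The labels give 14 samples in 5 groups: 3 labelling times with 3 libraries each, total RNA depleted of rRNA with 3 libraries, and a background group taken through the procedure without label, with 2 libraries. Replicate numbers in the deposited tables were read as the timecourse numbers of the labels. The label-free samples are titled timecourses 1 and 3, but their columns name no timecourse. These 2 libraries are therefore called replicates 1 and 2 and were paired with nothing. Both stayed in the fits that left out a timecourse. For 1 of them the source label reads as depleted total RNA while the title reads as background; the title set the group.

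The read counts per annotated feature were deposited by the authors as whole numbers that they had not normalised, per the file headers. The counting tool, the strand setting and the treatment of reads that match several places are not given in the sources used here. The table held 12549 rows, of which 100 repeated another row in full and were removed, leaving 12449 features; 14 RPKM columns were not used. Of 6688 protein-coding identifiers, 6005 matched a locus tag of the reference annotation, which gave symbols and R64 coordinates. Features cover protein-coding genes, CUTs (cryptic unstable transcripts), SUTs (stable unannotated transcripts), XUTs (transcripts stabilised without the exonuclease Xrn1), antisense RNAs and stable RNAs. Without a stated strand setting, values of CUTs, SUTs, XUTs and antisense features that overlap genes are uncertain, and so are those of near-identical copies (paralogous ribosomal protein genes, tRNA genes, rDNA repeats, both forms of the U5 snRNA).

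The authors also deposited, per the file headers, a ratio for each of 187 introns in every 4tU library, with the reads behind it. It lies between 0 and 1 and was read as the fraction of spliced transcript, because its median was higher at each later labelling time and highest at the steady state. The steady-state column is a single value made by the authors with no replicates, and how the ratio was estimated is not stated. Other intron values were deposited by the authors: the area under the splicing curve (AUC) for 117 introns, lengths, folding energies and base shares, and each splice-site motif score, which reaches 100 at most, per the file headers; the folding and scoring methods are not given in the sources used here. AUC values rebuilt from the fractions correlated with the deposited values at r = 0.9998 across the 117 introns. Tables of exon, intron and junction segments hold other values deposited by the authors, 1 per segment and group. Their headers say FPKM, but the values are far below the RPKM of the same genes, so the scale was taken as arbitrary and only ratios within a gene were used.

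Abundances were tested with edgeR 4.0.16 (R 4.3.3): features were kept by filterByExpr with a minimum count of 10, libraries were scaled with TMM factors, and the quasi-likelihood F test was adjusted by Benjamini-Hochberg over all features tested, with a threshold of 0.05. Comparisons of 4tU times with each other and with total RNA were fitted over those 4 groups, and comparisons with the label-free group over all 5. TMM sets the bulk of features to a median near 0, so changes are relative to that median. Intron fractions were tested as unspliced fractions (1 minus the spliced fraction) with limma 3.58.1 on the fraction itself, over 187 introns. Differences between introns of ribosomal protein (RP) genes and other introns, and relations to intron features, were tested two-sided with 100000 permutations over introns, which can give no p below 1e-05; introns are not independent replicates. Medians per library were compared by an exact two-sided permutation test. With 3 libraries against 3 that test cannot go below 0.10.

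Gene lists were fixed before the data were examined, as were the comparisons and the alternatives not described as added later. The 18 lists cover cytoplasmic RP genes, ribosome biogenesis, glycolysis and translation elongation, core histones, mitochondrial RP genes, nuclear oxidative phosphorylation genes, environmental stress, the cell cycle, pyrimidine metabolism, mitochondrially encoded genes, snoRNAs, spliceosomal snRNAs, RNA polymerase III and other stable RNAs, rRNA units, unannotated transcripts (CUTs, SUTs and XUTs), meiotic genes with introns, genes with autoregulated splicing or a snoRNA in the intron, and splicing and decay machinery. Lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists of each comparison. A count adjusted over the list alone treats the list as the whole family of tests.

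Named features follow a rule fixed at the same time: among features past the threshold whose groups did not overlap and whose mean lay above the lower quartile of those tested, the 8 largest rises and the 8 largest falls, plus up to 3 members of each list with the highest mean level. For introns the rule takes the 8 highest and 8 lowest fractions at 1.5 min, 7 introns fixed by name that had values (ACT1, RPL28, YRA1, GLC7, TUB1, TUB3 and DBP2; RPL30, RPS14B and RPL22B were also fixed and fall among the lowest), and extremes of the AUC. Names outside these rules are marked in the text.

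Replicate libraries were compared within each group to look for a library deposited more than once. The lowest chi-square per feature of any pair was 113, so no pair was counted as 1 library; this sets libraries against counting error only, and PCR copies of reads can raise it. Whether the timecourses were separate cultures is not stated in the labels; p-values then measure the spread between these samples, which may be technical. Same-numbered libraries deviated together from their group means: the lowest correlation was 0.610 over 9 pairs of 4tU libraries and 0.253 over 9 pairs of a 4tU with a total RNA library, against a median of −0.505 for 4tU libraries of different timecourses. The timecourse number therefore pairs the samples, and fits with it as a block were run as alternatives. Other alternatives were DESeq2 1.42.0 (its size factors inside edgeR, and its Wald test), library size as the only scaling, no filter, a filter at a mean count of 100, fits of the compared groups alone and fits without each timecourse. For introns they were a log2 ratio with a pseudocount of 0.01 or 0.1, the upper part by expression, and other intron sets.

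Tests were tried on simulated data. The simulated counts took a single spread for all features from the unblocked fit of the 4 groups, and held no timecourse effect. For 5 against 1.5 min, on 11445 features, edgeR recovered 0 of 50 changes of 2-fold, 10 of 50 of 4-fold, 28 of 50 of 8-fold and 48 of 50 of 16-fold, with 6 false calls. For 1.5 min against total RNA, on 11458 features, the numbers were 0, 8, 29 and 46 of 50, with 3 false calls. The limma test over 187 introns recovered 9 of 20 falls of 0.2, 17 of 20 of 0.4 and 20 of 20 of 0.6, with 2 false calls. Library totals ran from 3618310 to 65173280 counts, so counting error differed between libraries. Scripts ran on Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.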

Results

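Newly made RNA was marked in growing yeast with 4tU, a uracil analogue that cells build into RNA, and captured through its thiol group after 1.5, 2.5 or 5 min. Each labelling time had 3 libraries from timecourses 1, 2 and 3, with total RNA depleted of rRNA from the same timecourses (n = 3) and 2 libraries captured without label. Timecourses 1, 2 and 3 had total counts of 7438973, 14245489 and 25891855 at 1.5 min, 9596800, 12599524 and 18891399 at 2.5 min, and 7206103, 20528678 and 20371687 at 5 min. Total RNA had 3618310, 65173280 and 21361270 counts, and the label-free libraries 37181457 and 13627513. rRNA took 51.2% and 55.4% of the counts in the label-free libraries. The rRNA features RDN25-2 and RDN37-2 had identical mean levels at 1.5 and 2.5 min and the same log2 fold change between them (−0.056). The same reads may therefore stand in both. If so, the rRNA shares, the library totals and the list of rRNA units count them more than once. snoRNAs, the small nucleolar RNAs that guide rRNA modification and processing, took 9.87% ± 1.42 of the counts outside rRNA at 1.5 min, 11.8% ± 0.873 at 2.5 min and 14.2% ± 0.567 at 5 min (SD, n = 3). Their share was 24.9% ± 7.52 in total RNA (SD, n = 3) and 20.4% ± 4.92 without label (SD, n = 2). Total RNA replicate 3 stood apart from the other 2 total RNA libraries. Of its protein-coding features 12.9% were at 0, against 9.52% and 1.26%. snoRNAs took 33.6% of its counts outside rRNA, against 20.8% and 20.4%.

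The comparison of 1.5 min labelling with total RNA shows which RNAs take a larger share of the captured RNA than of the standing pool. Poorer capture of short RNAs and carry-over of unlabelled RNA can shift these shares and were not separated from the age of the RNA. Cryptic and other unannotated transcripts were the main class among the higher features, while snoRNAs, snRNAs and the abundant mRNAs of ribosomal proteins, glycolysis and respiration were lower. With library size as the only scaling the respiration median turned above 0, while the median of all features stood at 1.97. The group calls of unannotated transcripts, snRNAs and glycolysis genes were lost in the stricter group test (adjusted p = 0.184, 0.100 and 0.205 with an estimated correlation). The unannotated transcript CUT744 stood at 24 ± 6.13 CPM (normalised read count, with TMM-scaled library size) at 1.5 min and 0.667 ± 0.628 in total RNA (SD, n = 3 each). Its log2 fold change was 4.97 ± 0.77 (SE, edgeR adjusted p = 0.00162). The box H/ACA snoRNA snR44 (R64 chromosome XII, 856710 to 856920) had a log2 fold change of −5.49 ± 0.67 (SE, adjusted p = 0.000473), and RPP0 (YLR340W, chromosome XII, 805887 to 806825), the P0 protein of the ribosomal stalk, −2.77 ± 0.48 (SE, adjusted p = 0.0027). RPS14B, 1 of a pair of genes for ribosomal protein S14, went the other way, with 3019 ± 734 CPM at 1.5 min and 557 ± 96.4 in total RNA (SD, n = 3 each). The log2 fold change of RPS14B was 2.44 ± 0.38 (SE, adjusted p = 0.00164).

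edgeR's quasi-likelihood test called 2084 of 11513 features in this comparison, 773 higher and 1311 lower. With library size as the only scaling, the median log2 fold change of all features stood at 1.97 and the split became 6587 higher and 90 lower, so every change here is relative to the bulk of features. The count depended on which libraries were in the fit. It was 302 without timecourse 1, 0 without timecourse 2 and 3318 without timecourse 3, where each fit left out all libraries of that timecourse. Leaving out total RNA replicate 1 alone gave 2043 (618 higher and 1425 lower), close to the full count. Leaving out total RNA replicate 2 alone gave 3243, with more higher than lower (1705 and 1538), and leaving out replicate 3 alone gave 3782 (1740 and 2042). DESeq2's Wald test called 1800 higher and 1744 lower, so the surplus of lower features did not hold in every fit. RPP2A, PDC1, ATP1 and EGT2 lost their calls without total RNA replicate 1 (adjusted p = 0.0868, 0.0705, 0.0749 and 0.104) and without replicate 2 (adjusted p = 0.0842, 0.0604, 0.0585 and 0.0856).

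Of 4302 unannotated transcripts tested, 529 were higher and 211 lower (506 and 200 adjusted over the list alone), with a median log2 fold change of 0.71. The camera test gave an adjusted p of 1.6e-09 for them, and the call was lost at an adjusted p = 0.184 with an estimated correlation. CUTs had 237 of 1841 members higher and 95 lower, SUTs 101 of 819 higher and 29 lower, and XUTs 191 of 1642 higher and 87 lower. SUT285 had a log2 fold change of 4.88 ± 1.09 (SE) and XUT_13F-3 of 4.56 ± 0.90, while CUT831 was lower at −2.99 ± 0.45 (adjusted p = 0.0106, 0.00539 and 0.00141). Antisense features outside that list divided into 20 higher and 70 lower of 402. These features overlap genes and the strand setting of the counting is not stated, so their levels may hold reads of the gene across from them.

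snoRNAs fell as a group: 59 of 76 were lower and 0 higher (67 lower adjusted over the list alone), with a median of −4.09, which stayed below 0 at −1.99 with library size as the only scaling. For snoRNAs camera gave an adjusted p of 5.0e-37 (adjusted p = 0.0406 with an estimated correlation). snR53, a box C/D guide, stood at −5.95 ± 1.10 (SE, adjusted p = 0.00388), snR31 at −4.93 ± 0.52 (adjusted p = 0.000402) and snR17a, a copy of the U3 snoRNA needed to cleave pre-rRNA, at −2.90 ± 0.56 (adjusted p = 0.0049). All 6 spliceosomal snRNAs were lower, also 6 adjusted over the list alone, with a median of −3.21 and of −1.07 with library size only. For snRNAs camera gave an adjusted p of 1.7e-06 (adjusted p = 0.100 with an estimated correlation). Among them LSR1, the U2 snRNA, stood at −3.16 ± 0.63 and snR19, the U1 snRNA, at −2.82 ± 0.49. The lower side held 11 of 22 mitochondrially encoded genes (17 adjusted over the list alone), with a median of −3.99 and of −1.81 with library size only. Their camera adjusted p was 6.9e-10 (adjusted p = 0.299 with an estimated correlation). Among them the mitochondrial ribosomal RNAs 21S_rRNA and 15S_rRNA stood at −5.23 ± 1.40 and −5.17 ± 1.37. Without total RNA replicate 3 they stood at −3.25 and −2.83, and 15S_rRNA lost its call (adjusted p = 0.0471 and 0.0527). RNA polymerase III and other stable RNAs had 1 of 266 members higher and 13 lower (0 and 1 adjusted over the list alone). Their median was −2.61 and their camera adjusted p 1.8e-04 (adjusted p = 0.624 with an estimated correlation). SCR1, the RNA of the signal recognition particle, stood at −3.37 ± 0.78 (adjusted p = 0.012). edgeR called 0 of 10 rRNA units, and 0 adjusted over the list alone, at a median of −3.10 (camera adjusted p = 0.0286; adjusted p = 0.615 with an estimated correlation).

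Cytoplasmic RP genes were lower in 108 of 138 members and higher in 2 (122 and 4 adjusted over the list alone), with a median of −2.09 that was −0.14 with library size as the only scaling. For RP genes camera gave an adjusted p of 8.1e-37 (adjusted p = 0.00746 with an estimated correlation). RPP2A, a stalk protein, had a log2 fold change of −2.24 ± 0.68 (SE, adjusted p = 0.042), and RPS14A, the paralog of RPS14B (YJL191W, R64 chromosome X, 73787 to 74611), of −2.65 ± 0.49 (adjusted p = 0.00406). Reads can be shared between these copies. Of 26 genes of glycolysis and translation elongation, 23 were lower and 0 higher (24 lower adjusted over the list alone), with a median of −2.30 and of −0.38 with library size only. For this list camera gave an adjusted p of 2.5e-13 (adjusted p = 0.205 with an estimated correlation). TDH3, a glyceraldehyde-3-phosphate dehydrogenase gene on R64 chromosome VII, 882812 to 883810, stood at −3.37 ± 0.69 (adjusted p = 0.00681), the enolase gene ENO2 at −3.02 ± 0.74 (adjusted p = 0.0164) and the pyruvate decarboxylase gene PDC1 at −2.15 ± 0.62 (adjusted p = 0.0332). Nuclear genes of oxidative phosphorylation were lower in 19 of 38 members and higher in 0 (27 lower adjusted over the list alone), with a median of −1.31 that turned to 0.71 with library size only. For respiration genes camera gave an adjusted p of 3.6e-12 (adjusted p = 5.6e-04 with an estimated correlation). ATP1 and ATP2, the alpha and beta subunits of the mitochondrial ATP synthase, stood at −1.58 ± 0.45 and −2.40 ± 0.47 (adjusted p = 0.0331 and 0.00524), and ATP1 turned to 0.33 with library size only.

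Environmental stress genes had 0 of 40 members higher and 9 lower (2 and 10 adjusted over the list alone), with a median of −0.58 that turned to 1.32 with library size only. Their camera test gave an adjusted p of 0.0325, which was 0.0577 with the timecourse as a block and 0.624 as the adjusted p with an estimated correlation. HOR7, a gene induced by osmotic stress, stood at −1.65 ± 0.39 (SE, adjusted p = 0.014) and at 0.40 with library size only. Meiotic genes with introns had 2 of 15 members higher and 0 lower (3 and 0 adjusted over the list alone; median 1.03, camera adjusted p = 0.0246; adjusted p = 0.345 with an estimated correlation). Genes with autoregulated splicing or an intronic snoRNA had 3 of 18 higher and 7 lower (5 and 9 adjusted over the list alone). Their median was −0.62, and 1.26 with library size only, and their camera adjusted p 0.0612. Ribosome biogenesis genes had 1 of 120 higher and 6 lower (0 and 0 adjusted over the list alone, median −0.28, camera adjusted p = 0.243). Mitochondrial RP genes had 0 of 74 higher and 4 lower (0 and 0 adjusted over the list alone, median −0.16, camera adjusted p = 0.221).

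Core histone genes had 0 of 10 members higher and 2 lower, also 2 adjusted over the list alone (median −0.43, camera adjusted p = 0.243). HHT2, a histone H3 gene, stood at −1.61 ± 0.39 (SE, adjusted p = 0.0151) and at 0.50 with library size only, while HTA1, a histone H2A gene, had a log2 fold change of 0.67 that did not pass (adjusted p = 0.186). Cell cycle genes had 3 of 34 higher and 2 lower, the same numbers adjusted over the list alone (median 0.16, camera adjusted p = 0.316). CTS1, an endochitinase of cell separation, stood at −2.67 ± 0.44 (adjusted p = 0.00201), and EGT2, another gene of cell separation, at −1.49 ± 0.46 (adjusted p = 0.0428) and at 0.39 with library size only. Genes of pyrimidine metabolism had 2 of 19 higher and 3 lower (2 and 4 adjusted over the list alone, median −0.46, camera adjusted p = 0.243), with URA2, which carries out the opening steps of pyrimidine synthesis, at −2.20 ± 0.47 (adjusted p = 0.00841). Splicing and decay genes had 2 of 46 higher and 3 lower, the same numbers adjusted over the list alone; their median was 0.07, their mean −0.00 and their camera adjusted p 0.888. The helicase gene BRR2 had a log2 fold change of −2.67 ± 0.88 that did not pass (adjusted p = 0.0555) and passed at −1.89 with the timecourse as a block (adjusted p = 0.0255). HAC1 (R64 chromosome VI, 75179 to 76147), the transcription factor of the unfolded protein response, whose mRNA is cut by the endonuclease Ire1 in place of the spliceosome, was lower at −2.69 ± 0.41 (adjusted p = 0.00145).

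**Figure D1:**
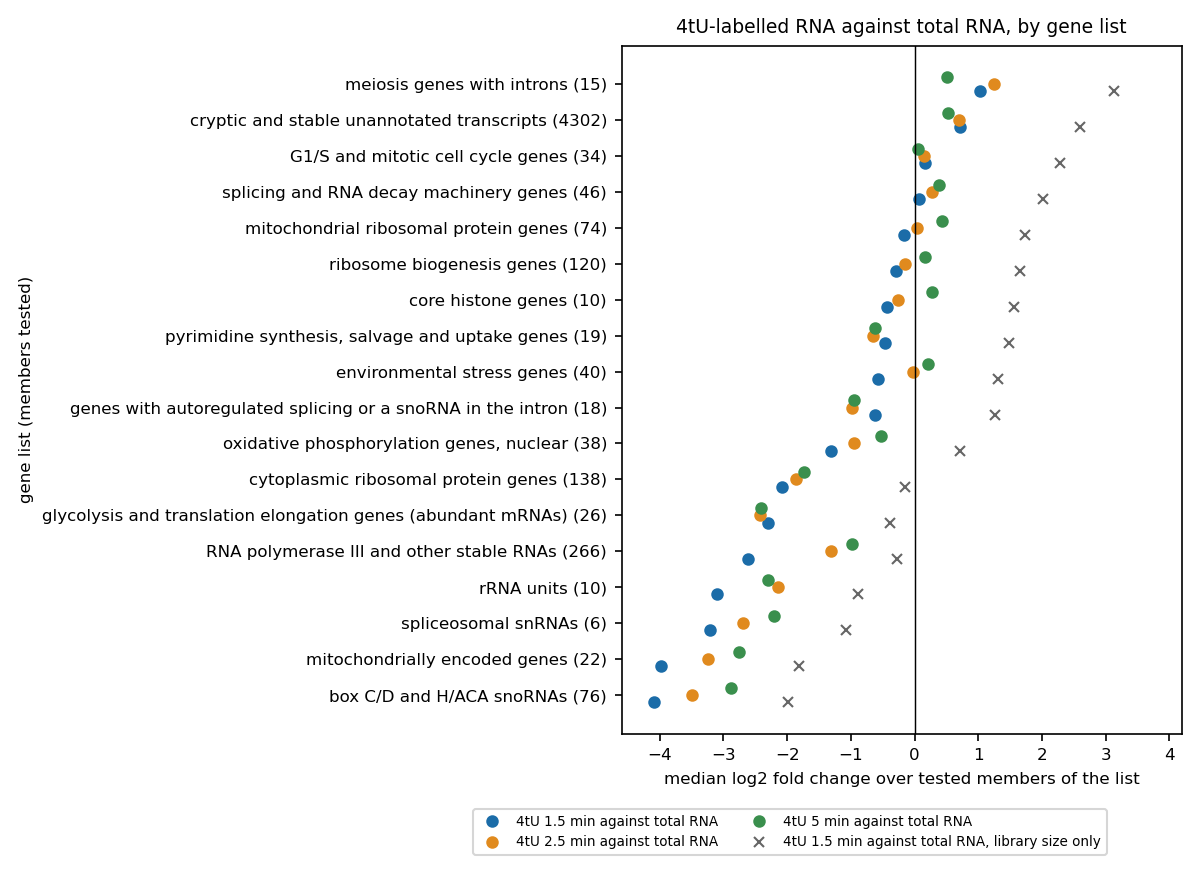
Median log2 fold change of each fixed gene list in 4tU libraries against total RNA (horizontal axis, log2) at 1.5, 2.5 and 5 min, from edgeR with TMM scaling over 3 libraries per group, with crosses for 1.5 min under library size as the only scaling. snoRNAs lie at −4.09, −3.50 and −2.87 and RP genes at −2.09, −1.86 and −1.73. With library size as the only scaling the RP medians were −0.14, 0.06 and 0.00. The medians of all features were then 1.97, 2.04 and 1.86, so RP genes stayed below the bulk of features.

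Labelling for 2.5 and 5 min was compared with the same total RNA libraries. At 2.5 min CUT744 had a log2 fold change of 5.00, snR44 of −4.75, RPP0 of −3.33, TDH3 of −3.39, HAC1 of −2.48 and RPS14B of 1.37 (adjusted p = 0.0278 for RPS14B). At 5 min CUT744 stood at 4.58, snR44 at −3.93, RPP0 at −3.19, TDH3 at −3.09 and HAC1 at −1.99, and RPS14B at 0.71 no longer passed (adjusted p = 0.211). TMA19, a gene for a protein bound to ribosomes, stood at −3.93 ± 0.37 (SE, adjusted p = 0.000783) and ZPS1, a gene regulated by zinc, at −3.90 (adjusted p = 0.00832) at 5 min. RP genes were lower in 102 of 138 members at 2.5 min and 98 at 5 min, with 1 and 0 higher (120 and 114 lower adjusted over the list alone). Their medians of −1.86 and −1.73 were 0.06 and 0.00 with library size only. Under that scaling the medians of all features stood at 2.04 and 1.86, so RP genes stayed below the bulk of features. Both RP calls held with an estimated correlation (adjusted p = 0.00785 and 0.00634). snoRNAs were lower in 52 of 76 members at 2.5 min and 43 at 5 min and higher in 0 (64 and 58 lower adjusted over the list alone). Both snoRNA calls held with an estimated correlation (adjusted p = 0.0471 and 0.0487). Oxidative phosphorylation genes were lower in 15 and 12 of 38 members (20 and 14 adjusted over the list alone), with medians of −0.95 and −0.52 that turned to 1.05 and 1.27 with library size only. Both respiration calls held with an estimated correlation (adjusted p = 0.00171 and 0.00634). Unannotated transcripts divided into 358 higher and 183 lower at 2.5 min and 207 higher and 161 lower at 5 min, with 294 and 167, and 116 and 132, adjusted over the list alone (adjusted p = 0.183 and 0.346 with an estimated correlation). Genes with autoregulated splicing or an intronic snoRNA had 1 of 18 higher and 7 lower at 2.5 min and 0 higher and 6 lower at 5 min (2 and 9, and 0 and 9, adjusted over the list alone). Their medians of −0.98 and −0.95 turned to 1.00 and 0.89 with library size only. Their camera adjusted p was 0.00582 at 2.5 min and 2.3e-04 at 5 min, and the call was lost at 2.5 min and held at 5 min in the stricter test (adjusted p = 0.0519 and 0.0179 with an estimated correlation).

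edgeR called 1733 features at 2.5 min, 559 higher and 1174 lower, and 1350 at 5 min, 375 higher and 975 lower. With library size only the splits were 6801 to 73 and 6046 to 65, and the medians stood at 2.04 and 1.86. The counts were 144 and 0 without timecourse 1, 0 and 0 without timecourse 2 and 2642 and 2190 without timecourse 3. Without total RNA replicate 2 alone they were 2992 and 2671, with more higher than lower (1621 and 1371 at 2.5 min, 1455 and 1216 at 5 min). Without replicate 3 alone they were 3388 and 2977 (1514 higher and 1874 lower, 1272 higher and 1705 lower). DESeq2's Wald test called 1566 higher and 1621 lower at 2.5 min and 1253 higher and 1488 lower at 5 min. Without total RNA replicate 1 the call of RPS14B at 2.5 min was lost (adjusted p = 0.0806).

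Labelling for 5 min was compared with 1.5 min to show which RNAs gain or lose share as labelling goes on. Mitochondrial RP genes (median log2 fold change 0.64) and oxidative phosphorylation genes (0.57) rose as groups, and so did snoRNAs (1.14), though not in the stricter group test (adjusted p = 0.138 with an estimated correlation). No single feature passed edgeR's test over all features in the fit of the 4 groups, with or without the timecourse as a block. RPS14B had the log2 fold change −1.73 ± 0.37 (SE, n = 3 each, edgeR adjusted p = 0.292), HSP82, an Hsp90 chaperone gene, 1.67 ± 0.51 (adjusted p = 0.511) and HOR7 1.50 ± 0.39 (adjusted p = 0.451), none of which passed in that fit without the block. edgeR called 0 of 11513 features, with 754 at an unadjusted p under 0.05 (449 higher, 305 lower), and DESeq2 called 139. With library size only edgeR also called 0, and the median of all features stood at −0.17. The 0 did not hold in fits chosen after the data were seen. Without total RNA replicate 3, which bears on this comparison through the shared estimate of spread, 312 features were called. The count was 370 in the 4tU libraries alone and 3279 there with the timecourse as a block (1709 higher, 1570 lower). In that blocked fit of the 4tU libraries all 10 features given in the text for this comparison passed, with adjusted p from 3.2e-04 for HSP82 to 0.0208 for HAC1. The naming rule gave more features than these 10. Over both comparisons among 4tU times, 23 pairs of a named feature and a comparison gained a call in that fit. Another 74 kept their direction and side of the threshold, and 9 changed sign. Without a block RPS14B passed in the 4tU libraries alone (adjusted p = 0.0429), and RPS14B and HOR7 passed without total RNA replicate 3 (adjusted p = 0.0349 and 0.0464) and in DESeq2's Wald test (adjusted p = 0.00013 and 0.0422).

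snoRNAs had 0 of 76 members called and 1 adjusted over the list alone. In the 4tU libraries alone with the timecourse as a block, 54 of 76 snoRNAs, 41 of 74 mitochondrial RP genes and 22 of 38 oxidative phosphorylation genes were higher and 0 lower. Within timecourses 1, 2 and 3 the ratio of 5 to 1.5 min was above 1 for 64, 69 and 72 of 76 snoRNAs. Their group test passed with camera alone (adjusted p = 5.4e-15). With library size only their median was 0.93. snR190, a box C/D guide, had a log2 fold change of 1.08 that did not pass in the fit of the 4 groups. Mitochondrial RP genes passed in both tests (adjusted p = 8.5e-12 with camera; adjusted p = 0.0339 with an estimated correlation), with 0 of 74 called and 0 adjusted over the list alone, and their median was 0.42 with library size only. Oxidative phosphorylation genes passed in both tests as well (adjusted p = 7.3e-11 with camera; adjusted p = 8.3e-04 with an estimated correlation), with 0 of 38 called, 7 higher adjusted over the list alone and a median of 0.36 with library size only. The stable RNAs of RNA polymerase III (median 1.63), mitochondrially encoded genes (1.03), snRNAs (0.99), histones (0.85), stress genes (0.82) and RP genes (0.29) rose in the camera test (adjusted p from 3.8e-08 to 0.0059). None of these 6 calls held with an estimated correlation (adjusted p = 0.513, 0.441, 0.181, 0.138, 0.321 and 0.441 with an estimated correlation, in that order). Adjusted over the list alone, 7 stress genes were higher and 1 lower, 2 histone genes were higher, and 0 members of the other 4 lists passed. In the 4tU libraries alone with the block, 120 of 246 RNA polymerase III RNAs and 18 of 22 mitochondrially encoded genes were higher and 0 lower. So were 6 of 6 snRNAs and 7 of 10 histone genes. Stress genes had 16 of 40 higher and 3 lower there, and RP genes 39 of 138 higher and 14 lower. The values of 15S_rRNA at 1.07, snR7-L, the long U5 snRNA, at 1.18 and HHT2 at 1.00 did not pass in the fit of the 4 groups.

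Splicing and decay genes had a median of 0.27 (camera adjusted p = 0.0238, lost at 0.0637 with the timecourse as a block; adjusted p = 0.441 with an estimated correlation). Unannotated transcripts had a median of −0.21 and 0 of 4302 called, 0 adjusted over the list alone (camera adjusted p = 3.4e-07; adjusted p = 0.310 with an estimated correlation). Genes with autoregulated splicing or an intronic snoRNA had a mean of −0.35 and a median of −0.00, with 0 of 18 called and 3 lower adjusted over the list alone (camera adjusted p = 0.00598; adjusted p = 0.103 with an estimated correlation). NOP10, a protein of box H/ACA particles, at 1.20, HAC1 at 0.70 and MEI4, a gene of meiotic recombination whose transcript holds an intron, at −1.08 did not pass in the fit of the 4 groups. In the 4tU libraries alone with the block, unannotated transcripts had 240 of 4242 members higher and 836 lower. There splicing and decay genes had 11 of 46 higher and 3 lower, and genes with autoregulated splicing or an intronic snoRNA 2 of 18 higher and 8 lower.

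Between 2.5 and 1.5 min edgeR called 0 of 11513 features, with 101 at an unadjusted p under 0.05, and DESeq2 called 0; the 4tU libraries alone with the timecourse as a block gave 139. Oxidative phosphorylation genes had a median of 0.29 (camera adjusted p = 5.3e-06; adjusted p = 0.00827 with an estimated correlation), with 0 of 38 called. With the timecourse as a block 4 more lists passed the camera test: RP genes (adjusted p 0.0515 without and 0.0416 with the block), glycolysis and elongation genes (0.166 and 0.0154), pyrimidine genes (0.0929 and 0.0293) and rRNA units (0.251 and 0.033). None of these 4 passed in the stricter test, run without the block (adjusted p = 0.644, 0.722, 0.378 and 0.722 with an estimated correlation).

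The libraries titled as background were read as RNA that binds the beads unlabelled, and 1.5 min labelling was compared with them. Label-free replicate 1 stood close to total RNA, with a Spearman rho of 0.951 with its replicate 2 and 0.925 with its replicate 1. Its rho was 0.735 with total RNA replicate 3 and 0.788 with label-free replicate 2. Its rRNA share was 51.2%, against 28.7% at most in total RNA. The columns do not show which label-free library has the source label of depleted total RNA, so its content stays open. CUT811 had a log2 fold change of 4.91 (edgeR adjusted p = 0.0169), CUT285 of 4.55 (adjusted p = 0.00972) and CUT306 of 4.47, all higher with label (n = 3 against 2). RPS14B was higher with label at 2.91 (adjusted p = 0.0159) and its paralog RPS14A lower at −2.59 (adjusted p = 0.0365). snR53 at −5.44, snR40 at −4.48 and snR44 at −4.30, all snoRNAs, were lower with label, as were snR7-L at −3.02 and CUT831 at −2.97. CTS1 was lower at −2.37 (adjusted p = 0.0313) and stood at 0.18 with library size only. Of 11688 features, 560 were called, 168 higher and 392 lower. With library size only the split was 6005 to 10 and the median stood at 2.26. The count was 0 without timecourse 1 or timecourse 2, 962 without timecourse 3 and 2662 without total RNA replicate 3 alone (1210 higher, 1452 lower). DESeq2's Wald test called 909 higher and 954 lower. Without label-free replicate 1, which leaves 1 library in that group and takes the spread from the other groups, CUT811, snR53, snR40, CTS1 and RPS14A lost their calls (adjusted p = 0.0555, 0.174, 0.0604, 0.109 and 0.180), with snR53 at −2.90 and RPS14A at −1.43.

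snoRNAs were lower in 37 of 76 members (65 adjusted over the list alone), with a median of −3.30 and of −0.88 with library size only (camera adjusted p = 4.8e-39; adjusted p = 0.118 with an estimated correlation). RP genes were lower in 38 of 138 and higher in 2 (95 and 3 adjusted over the list alone), with a median of −1.57 that turned to 0.95 with library size only (camera adjusted p = 9.8e-22; adjusted p = 0.219 with an estimated correlation). Glycolysis and elongation genes were lower in 5 of 26 (17 adjusted over the list alone), and their median of −1.90 turned to 0.74 with library size only (camera adjusted p = 1.0e-08; adjusted p = 0.365 with an estimated correlation). Unannotated transcripts divided into 114 higher and 63 lower of 4403 (101 and 58 adjusted over the list alone), with a median of 0.47 (camera adjusted p = 2.8e-09; adjusted p = 0.219 with an estimated correlation). edgeR called 0 of 10 rRNA units with 9 lower adjusted over the list alone, at a median of −4.69 (camera adjusted p = 6.5e-07; adjusted p = 0.252 with an estimated correlation).

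Without label against total RNA, edgeR called 0 of 11688 features, with 1233 at an unadjusted p under 0.05 (736 higher, 497 lower), and DESeq2 called 102. Label-free replicate 1 correlated most with total RNA replicate 2, as given above, which bears on that count of 0. Without label-free replicate 1 a single library stood for that group, assumed to vary like the other groups, and 462 features were called (326 higher, 136 lower), MRPL36 among them (log2 fold change −2.64, adjusted p = 0.0102). With label-free replicate 2 left out in the same way 0 were called. With library size only the median of all features stood at −0.47. RDN18-2, a copy of the 18S rRNA gene, had a log2 fold change of 2.71 (adjusted p = 0.537), and the mitochondrial ribosomal protein genes MRPS18 and MRPL36 had 1.36 and −1.36 (adjusted p = 0.438 for both), so none passed with both libraries. RP genes had a median of −0.43 (camera adjusted p = 1.9e-09; adjusted p = 0.529 with an estimated correlation), which was 0.00 without label-free replicate 2, again with 1 library left. rRNA units had a median of 1.61 (camera adjusted p = 0.00154; adjusted p = 0.529 with an estimated correlation).

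The deposited ratio, read as the spliced fraction of each intron, was compared between RNA of each age. Its rise with labelling time was the reason for that reading, so the direction is not independent evidence of splicing. The median over 187 introns was 0.350, 0.507 and 0.420 at 1.5 min, 0.548, 0.690 and 0.538 at 2.5 min and 0.735, 0.824 and 0.741 at 5 min in timecourses 1, 2 and 3, against the authors' pooled 0.945 at the steady state. RPS18A, a gene of the small ribosomal subunit, changed by −0.333 ± 0.0285 in unspliced fraction from 1.5 to 5 min (SE, n = 3 each, limma adjusted p = 0.000533), RPL25 changed by −0.392 and RPL14B by −0.687. SEC14, the phosphatidylinositol transfer protein, had −0.443 ± 0.0739 (adjusted p = 0.00547). Introns of RPS14B, MPT5 and GCR1 stayed near 0 in every 4tU library at 1.5 and 2.5 min.

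The mean over libraries of the median unspliced fraction was 0.574 ± 0.0787 at 1.5 min, 0.408 ± 0.0850 at 2.5 min and 0.233 ± 0.0497 at 5 min (SD, n = 3 each). The exact permutation test between 1.5 and 5 min gave p = 0.1, the smallest it allows. limma called 81 of 187 introns between 5 and 1.5 min, 79 with a lower and 2 with a higher unspliced fraction, and 99 had an unadjusted p under 0.05. RP introns held 55 of the lower calls among 86 and other introns 24 among 101. The count was 9, 46 or 50 without timecourse 1, 2 or 3. Between 2.5 and 1.5 min 9 introns were called, all lower and all in RP genes (RPS18A, RPL25, RPL14B, RPS0B, RPP1B, RPL23B, RPL27A, RPS17A and RPL34A). Both introns with a higher unspliced fraction at 5 min lie outside RP genes: PHO85, a cyclin-dependent kinase, at 0.0823 ± 0.0252 (adjusted p = 0.0348), and CMC4, a protein of the mitochondrial intermembrane space, at 0.388 ± 0.131 (adjusted p = 0.0476). RPS18A, RPL25, RPL14B, SEC14, CMC4 and the other introns called at 2.5 min were named after their values were seen.

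The lowest fractions at 1.5 min belonged to MPT5, an RNA-binding protein of the Puf family (0.001 ± 0.001 spliced, SD, n = 3; intron at R64 chromosome VII, 167355 to 167994), RPL22B (0.00133 ± 0.000577; chromosome VI, 64600 to 64920), and RPS14B (0.00133 ± 0.00231; chromosome X, 73797 to 74204). Next came RFA2 (0.00267 ± 0.00153), STO1 (0.00367 ± 0.00231), NMD2 (0.004 ± 0.00265), GCR1 (0.00467 ± 0.00404) and RPL30 (0.009 ± 0.0156; chromosome VII, 439094 to 439323). STO1 encodes the large cap-binding subunit, NMD2 a factor of nonsense-mediated decay and GCR1 the activator of glycolytic genes. At the steady state the authors' pooled values were 0.84 for RPS14B, 0.907 for RPL30 and 0.526 for GCR1, and 0.002 for MPT5, 0.027 for RPL22B and 0.031 for NMD2. The highest fractions were those of RPL37B (0.980 ± 0.00625; chromosome IV, 1450458 to 1450846), RPL31A (0.945 ± 0.0314), PHO85 (0.936 ± 0.00907), RPL37A, RPL20A, RPS6B, RPS21A and RPS27B, the last at 0.911 ± 0.0114.

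Among the introns fixed by name, ACT1, the actin gene (chromosome VI, 54378 to 54686), stood at 0.483 ± 0.173 at 1.5 min, lower at 0.319 ± 0.0705 at 2.5 min and at 0.696 ± 0.103 at 5 min (SD, n = 3 each; adjusted p = 0.100, not passed). TUB1, an alpha-tubulin gene, went from 0.222 ± 0.144 to 0.518 ± 0.136 (adjusted p = 0.0348). RPL28 stood at 0.109 ± 0.0789 and 0.378 ± 0.220 and the protein phosphatase gene GLC7 at 0.193 ± 0.126 and 0.407 ± 0.136. The export factor gene YRA1 stood at 0.0837 ± 0.0595 and 0.241 ± 0.196, TUB3 at 0.0350 ± 0.0361 and 0.0993 ± 0.104, and the helicase gene DBP2 at 0.236 ± 0.242 and 0.183 ± 0.157. None of these 5 passed. At 2.5 min the fractions were 0.291 for TUB1, 0.186 for RPL28, 0.248 for GLC7, 0.124 for YRA1, 0.0213 for TUB3 and 0.194 for DBP2. In the deposited AUC the lowest values among introns were 0.060 for UBC9, the SUMO-conjugating enzyme, and 0.069 for SEC27, a coatomer subunit. PFY1, profilin, went from 0.0377 ± 0.0345 to 0.401 ± 0.145 (adjusted p = 0.00811) and YOP1, a protein that shapes the endoplasmic reticulum, from 0.0467 ± 0.0472 to 0.400 ± 0.125 (adjusted p = 0.00766), with 0.0340 and 0.0727 at 2.5 min.

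**Figure D2:**
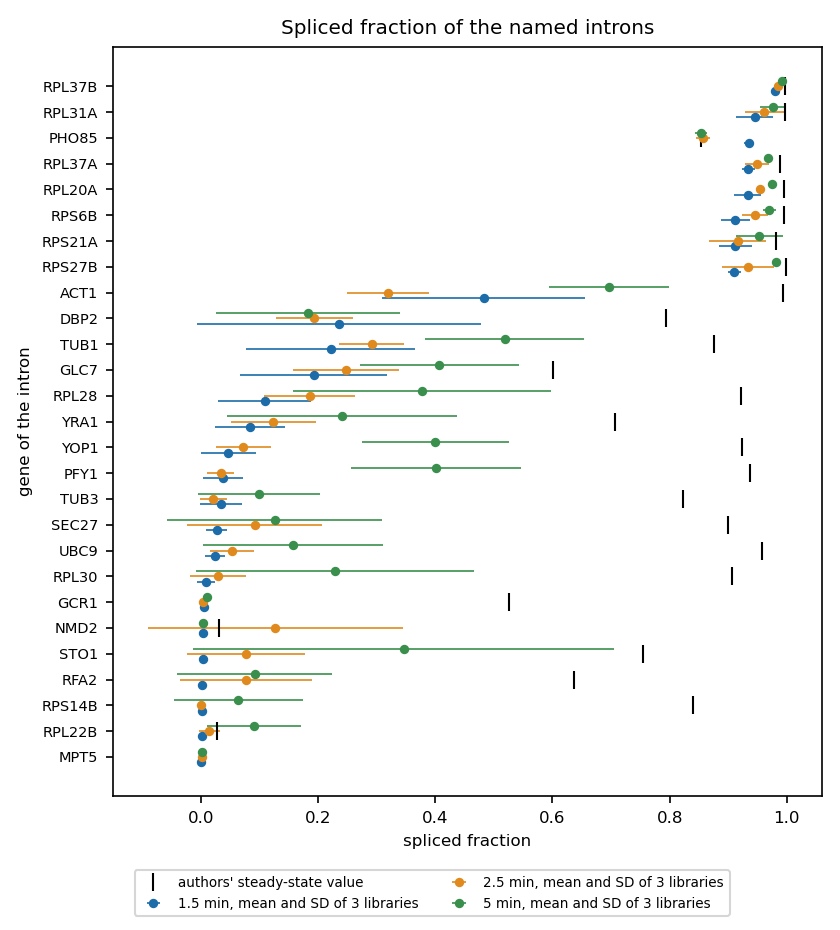
Spliced fraction (horizontal axis, 0 to 1) of named introns at 1.5, 2.5 and 5 min, with means as points and SDs over 3 libraries as bars, and the authors' pooled steady-state value as a tick. RPL37B lies at 0.980 at 1.5 min, while RPS14B lies at 0.00133 at 1.5 min and at 0.84 at the steady state.

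Against the steady state, the unspliced fraction at 1.5 min was higher by 0.519 ± 0.0787 (SD of the library medians, n = 3; 0.438 to 0.595). It was above the authors' pooled steady-state value in all 3 libraries for 175 of 187 introns and below it in all 3 for 3 introns. Ratios of deposited segments within protein-coding genes, which do not rest on that reading of the deposited ratio, gave the label-free values too. The junction share over 207 genes had a median of 0.242 at 1.5 min, 0.384 at 2.5 min and 0.597 at 5 min, against 0.778 without label and 0.762 in total RNA. The ratio of intron to exon signal over 233 genes was 0.60, 0.435 and 0.267 at 1.5, 2.5 and 5 min, against 0.030 without label and 0.031 in total RNA. These are the authors' group values with no replicates.

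Introns of RP genes were more spliced than other introns at every labelling time. The median spliced fraction over 86 RP introns was 0.681 at 1.5 min, 0.829 at 2.5 min and 0.913 at 5 min, against 0.223, 0.320 and 0.530 over 101 other introns, and 0.982 against 0.869 at the steady state. The difference was 0.458 at 1.5 min, 0.509 at 2.5 min and 0.383 at 5 min (permutation p = 1e-05 each, the smallest the permutations can give), and 0.113 at the steady state. At 1.5 min it had the same sign in all 3 timecourses, with 0.62 against 0.156, 0.764 against 0.32 and 0.659 against 0.193. The AUC differed by 0.319 between 83 RP introns and 34 others. The median of the rises of single introns from 1.5 to 5 min was 0.223 in RP introns and 0.202 in the others. That difference of 0.021 did not pass (permutation p = 0.336). The class medians given above rose more in the other introns, and RP introns started nearer to the upper limit, so equal rises are not shown. RP introns were longer, with a median of 403 nt against 97 nt.

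**Figure D3:**
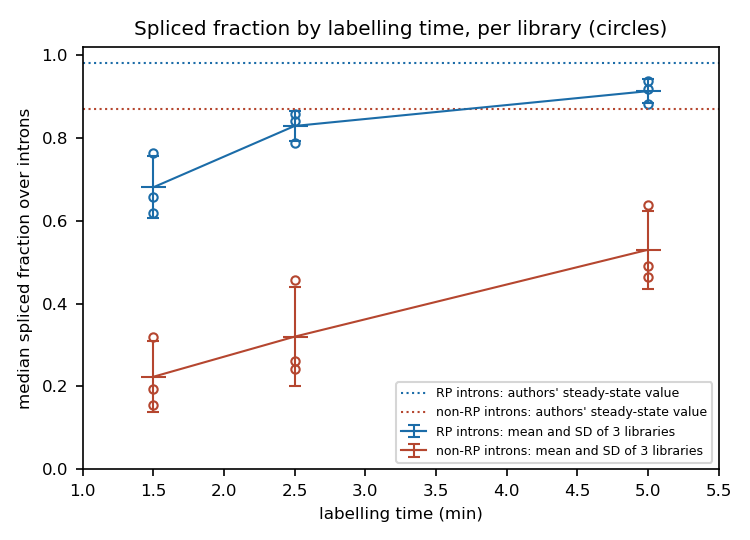
Median spliced fraction per library (vertical axis, 0 to 1) against labelling time in minutes, for 86 RP introns and 101 other introns, with circles for the 3 timecourses, means and SDs over 3 libraries, and the authors' pooled steady-state value as a dotted line. RP introns lie above other introns in each of the 9 libraries, with class medians of 0.681 and 0.223 at 1.5 min.

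Of 34 relations between splicing measures and intron features, computed across introns, 19 passed the adjustment. The AUC went with the share of A in the intron (Spearman rho 0.646, Pearson r 0.540 over 117 introns, permutation p = 1e-05, adjusted p = 4.25e-05 for rho). It went against the share of U (rho −0.466, r −0.385) and with intron length (rho 0.413, r 0.465). The spliced fraction at 1.5 min went against the length of exon 2 (rho −0.485, r −0.462 over 186 introns) and with steady-state reads (rho 0.405, r 0.406) and intron length (rho 0.326, r 0.323). Most of these relations did not pass within a class. Within RP introns alone 4 passed, among them the AUC with the share of A (rho 0.599) and of U (rho −0.388), while over 34 other introns these were 0.0864 and 0.0185 (adjusted p = 0.761 and 0.917). The remaining relations that passed in RP introns were the AUC with the folding energy per bp. Its rho was 0.456 for the whole intron and 0.477 from the intron start to the branch point. Over all 117 introns these were −0.0114 and −0.0445 and did not pass. The AUC had a rho with intron length of 0.0616 in RP introns and −0.399 in the others (adjusted p = 0.733 and 0.0888). Within other introns alone 4 relations of the spliced fraction passed, among them exon 2 length (rho −0.534) and intron length, whose sign turned (rho −0.278). In RP introns these were −0.239 and 0.0932 and did not pass. The spliced fraction had a rho with steady-state reads of 0.156 in RP introns and −0.140 in the others, and neither passed (adjusted p = 0.393 and 0.303). Differences between the classes were not tested.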

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

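Of the tests in this part, those of unlabelled RNA for the snoRNAs and of sequencing depth for total RNA replicate 3, the fit of the 4tU libraries alone, and the counts over other splits of the libraries, were chosen after the results were seen.

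The ratio of intron to exon signal in tRNA genes was above the label-free level, in deposited values that none of the comparisons used. Its median over 49 tRNA genes was 0.128 at 1.5 min, 0.211 at 2.5 min and 0.375 at 5 min, with 0 without label and 0 in total RNA, and the ratio exceeded the label-free value in 29, 30 and 32 of the genes. These are the authors' group values on an arbitrary scale, and tRNA gene copies share reads. The junction share over 41 tRNA genes had a median of 0 in every group, total RNA included. These values therefore registered little spliced tRNA. The ratio's median of 0 without label and in total RNA is the lowest value possible.

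snoRNAs had a higher share at 5 than at 1.5 min of labelling, with a median log2 fold change of 1.14 and 0 of 76 members past the threshold in the test over all features, or 54 in the 4tU libraries alone with the timecourse as a block. More carry-over of unlabelled RNA at 5 min would raise rRNA as well, which took 51.2% and 55.4% of the counts without label. The rRNA share at 5 min minus that at 1.5 min was −5.11, 3.54 and −5.05 percentage points in timecourses 1, 2 and 3 (mean −2.21, SD 4.98). The timecourses went both ways. Newly made rRNA can carry label too, so the rRNA share does not measure carry-over alone and cannot decide. Carry-over stays open. Poorer capture of short RNAs at brief labelling stays open, since the fold change had a Spearman rho of −0.0944 with length over the 76 snoRNAs (bootstrap SD 0.123, permutation p = 0.417). Slow release of mature snoRNAs from their precursors is a biological explanation that was not tested.

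RP introns were more spliced than other introns at 1.5 min, by 0.458. In introns within the range of read counts that both classes share the difference was 0.517 (83 RP, 40 other). Counts were not matched inside that range, and over all introns their medians were 2612 in RP and 533 in other introns. Read depth of the transcripts therefore stays open. In introns of at least 200 nt it was 0.652 (84 RP, 16 other), so the difference was not confined to short introns. The cut did not match the classes in length above 200 nt. Among the other introns longer ones were less spliced, so the cut can widen the difference. RP introns were the longer class (median 403 against 97 nt). For the other introns that relation therefore argues against greater length as the source of the higher RP fractions. In RP introns the relation with length did not pass (rho 0.0932), so for them the values do not decide. The method behind the deposited fraction stays open, as do other features that differ between the classes. Faster splicing of RP transcripts is a hypothesis that the design cannot separate from these.

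Total RNA replicate 3 stood apart from replicates 1 and 2, with 12.9% of protein-coding features at 0 against 9.52% and 1.26%. It had 5756523 protein-coding counts against 1629621 in replicate 1, so lower depth cannot account for its larger share at 0 beside replicate 1 (95% Wilson intervals 12.2 to 13.8% and 8.84 to 10.3%, for counting error only). Replicate 2 was the deepest, with 34061862 protein-coding counts, and depth stays open for part of the gap to it. In replicate 3 an rRNA share of 28.7% and a snoRNA share of 33.6% of the other counts leave RNA quality and depletion of rRNA open. The rRNA share was also high in the 4tU libraries of timecourse 3, at 25.4%, 21.8% and 20.4% after 1.5, 2.5 and 5 min. It is therefore not particular to this total RNA library. No biological explanation was tested, since the labels name none.

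Splits of 3 libraries against 3 number 10, too few for a share under 0.05. For 1.5, 2.5 and 5 min against total RNA the real splits gave 2084, 1733 and 1350 features and the highest of the other splits 0, so 1 of 10 splits gave as many. For 2.5 and 5 min against 1.5 min the real splits and the highest of the others gave 0 each, so all 10 gave as many. With a real count of 0 no other outcome was possible, so these splits decide nothing. They were fitted without the block, under which the 4tU libraries alone gave 139 and 3279. For introns between 5 and 1.5 min the real split gave 81 and the highest of the others 0, so 1 of 10 gave as many.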

How the results depend on the processing

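Added after the data were seen were the fits without single total RNA or label-free libraries, those of the 4tU libraries alone, and the block without the total RNA of timecourse 3. DESeq2's size factors, no filter and a stricter filter kept every count of features within 1.5 times its value. Comparisons are listed below in the order 1.5, 2.5 and 5 min against total RNA, 2.5 and 5 against 1.5 min, 1.5 min against no label, and no label against total RNA.

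With library size as the only scaling 6677, 6874 and 6111 features were called against total RNA and 6015 for 1.5 min against no label, because the whole distribution moved up. Under it HHT2 turned to 0.50, ATP1 to 0.33, HOR7 to 0.40 and EGT2 to 0.39 for 1.5 min against total RNA, and CTS1 to 0.18 for 1.5 min against no label. With only the compared groups in the fit the counts were 418, 392 and 175 against total RNA and 0 against no label, with fewer samples to estimate the spread. DESeq2's Wald test called 3544, 3187 and 2741 against total RNA, 0 and 139 among 4tU times, 1863 for 1.5 min against no label and 102 for no label against total RNA; the cause was not tested.

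Leaving out a timecourse or a library gave 0 to 3782, 0 to 3388 and 0 to 2977 against total RNA, 0 to 0 for 2.5 and 0 to 312 for 5 against 1.5 min, 0 to 2662 for 1.5 min against no label and 0 to 462 for no label against total RNA, where leaving out a label-free library leaves 1 that is assumed to vary like the other groups. The 4tU libraries alone gave 0 and 370. Leaving out total RNA replicate 3 raised the counts against total RNA, for 5 against 1.5 min and for 1.5 min against no label, while 2.5 against 1.5 min and no label against total RNA stayed at 0. Without timecourse 2 all 7 counts were 0. Leaving out only its total RNA library, the deepest, gave 3243, 2992 and 2671 against total RNA. Loss of that library alone therefore did not bring these counts to 0. The cause was not tested.

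The replicate block on the timecourse gave 2762, 2433 and 2022 against total RNA, each within 1.5 times of the value without it, and 0 and 0 among 4tU times. In the 4tU libraries alone it gave 139 and 3279. Without the total RNA of timecourse 3 the block gave 5279, 4872 and 4516, and 50 and 2653. No paired analysis was possible for the label-free group because its columns carry no timecourse. For lists the block moved camera calls from 52 to 57; besides the list calls given beside their values, it brought pyrimidine genes (adjusted p = 0.0375), RNA polymerase III RNAs (adjusted p = 0.00313) and rRNA units (adjusted p = 0.016) past the threshold for 5 min against total RNA, and it changed no other list call. These 3 did not pass without the block in the stricter test (adjusted p = 0.211, 0.871 and 0.688 with an estimated correlation).

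Of 126 list tests 70 passed with camera's preset correlation, 13 with an estimated correlation and 38 with fry. For introns between 5 and 1.5 min, leaving out a timecourse gave 9 to 50 calls, the block 107, a log2 ratio 96 and 91 with a pseudocount of 0.01 and 0.1, and the upper part by expression 58 of 93. The difference of 0.519 from the steady state was 0.379 in the upper part by expression, 4.31 on the log2 scale and 3.12 there with 0.1 as pseudocount, on other scales; without a timecourse it was 0.482 to 0.560. No replicate block applied there because the steady-state value is a single pooled one. The RP difference of 0.458 was 0.314 as a mean, 0.464 in genes with 1 intron, 0.517 at shared expression and 0.454 to 0.465 without a timecourse. Relations with features numbered 4 in RP introns alone and 4 in the others alone, with fewer introns, and 19 without the 2 farthest introns.

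Over 437 pairs of a named feature and a comparison, 6324 other values were computed: 5209 kept direction and side of the threshold, 529 lost it, 276 gained it and 310 changed sign, 96 of these under library size only. Among the 143 pairs that passed, 8 changed sign, all under library size only. In data simulated with the spread of the unblocked fit of the 4 groups and no timecourse effect, 0 of 50 changes of 2-fold were recovered. This limits what the counts of that fit can show. It does not cover the 4tU libraries alone with the timecourse as a block. There HAC1 passed for 5 against 1.5 min at a log2 fold change of 0.658 (edgeR adjusted p = 0.0208). The pseudocount planned for normalised abundances was not run, because counts were used.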

Other observations

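The test of paralogous gene pairs in this part was chosen after some of the fractions were seen, and the introns named here outside the fixed rule were picked after their values were seen.

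Some paralogous RP genes had spliced fractions far apart at 1.5 min, a difference that was not tested pair by pair. In 6 of 40 pairs the fractions were more than 0.5 apart. RPS14A, at 0.869, and RPS14B, at 0.00133, were 0.868 apart, the widest pair. RPL31A stood at 0.945 and RPL31B at 0.131, RPL22A at 0.796 and RPL22B at 0.00133, RPS19B at 0.796 and RPS19A at 0.0987, RPL16B at 0.838 and RPL16A at 0.171, and RPL33A at 0.816 and RPL33B at 0.273. The same RPS14 pair parted in abundance, with RPS14B at a log2 fold change of 2.44 and RPS14A at −2.65 for 1.5 min against total RNA.

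If members of a pair were spliced alike, the fraction of a gene would go with that of its paralog. Over the 40 pairs Spearman's rho was 0.143 (permutation p = 0.377), and the median absolute difference was 0.203. The pairs leave open whether paralogs are spliced alike, since reads shared between near-identical copies may blur both fractions.

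Timecourse 2 had the highest median spliced fraction at each labelling time, 0.507, 0.690 and 0.824, against 0.350, 0.548 and 0.735 in timecourse 1 and 0.420, 0.538 and 0.741 in timecourse 3. The range between libraries exceeded the sum of the 2 widest deposited 95% interval values for 76, 76 and 71 of 187 introns at 1.5, 2.5 and 5 min. Whether that value is the whole width of the interval or its distance from the estimate is not stated. As a distance, exceeding the sum means intervals that do not overlap, and as a width it asks for a larger gap than that.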
